A study of Mus musculus with 9 samples.

How the data were processed

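Total RNA was taken from secondary mouse embryonic fibroblasts at the start of reprogramming (day 0) and from adherent and suspension cultures on days 2, 6, 15 and 25, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited values are log2 expression per probe set, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, applies quantile normalization and summarises the probes of a probe set over all arrays. Its version is not given in the sources used here. The log base is not stated and was read as log2 from the range of 2.06 to 14.76. Because RMA brings the arrays to a shared distribution, a change in total RNA per cell is not measured. Each pair of arrays held between 1.56% and 4.08% of probe sets with exactly the same value, and between 80.4% and 92.9% of these lay below the median level.

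The value table held 35557 probe sets. The platform annotation, which can be old, gave 1 gene symbol for 21789, several for 1621 and none for 12147. Probe sets with several symbols or none were not named. Entrez identifiers of 21698 named probe sets were in the RefSeq gene table, and 0 symbols changed. Of the 19938 genes, 999 had more than 1 probe set, and the probe set with the highest mean stood for the gene. Genes whose mean lay below the 30th percentile of all probe set means (6.37) were left out, which left 15710. Some genes of the lists had no row with their name and were not analysed here. Gene coordinates are not given because the sources used here name no build.

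Groups came from the sample labels, with 1 array per group. The labels do not say whether the arrays came from separate cultures. limma 3.58.1 in R 4.3.3 was used, with lmFit and eBayes with a variance trend, two-sided tests, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Culture was tested over the 8 arrays of days 2 to 25 with day as a block, leaving 3 residual degrees of freedom. Days were compared over all 9 arrays with culture as a covariate, also with 3. The day 0 array, which belongs to neither culture, was entered in this covariate as adherent, so a change from day 0 is one to the fitted adherent level and not to the mean of both arrays of a day. The change of the culture difference between early and late days left 2. The spread in the culture and day fits is the departure from the additive model, that is how far the culture difference varied from day to day. In the fit of the change it is how far that difference varied within the early days and within the late days. Neither is the spread between replicate cultures. The adjusted p-values cover only these departures. Single-day differences are plain differences of 2 log2 values; each list's median was placed among 10000 random lists of the same size matched on mean expression, as a description of those arrays.

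Gene lists were fixed before the data were examined, 36 in number, of which 34 had at least 5 genes tested. Each was tested with camera at a preset correlation between genes of 0.01 and again with the correlation estimated, adjusted over lists within a comparison. With the preset value 86 calls were made over the 7 comparisons, and 0 of them held with the estimated correlation. The estimated form rests on the 3 or 2 residual degrees of freedom of the fit, so a missing call there does not show an unchanged list. Members were counted over all genes and adjusted over the list alone.

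The genes named in the text also followed a rule fixed before the data were examined. For the culture comparison it took the 10 highest and 10 lowest genes past the threshold with one sign on all 4 days, or, with fewer than 5 in a direction, the 10 with the smallest p, given as not having passed. For each day comparison it took the 10 largest changes each way past the threshold, for each single day the 5 largest each way, and for each list 2 to 4 members with the largest change. Pou5f1, Sox2, Klf4, Myc, Nanog, Cdh1 and Thy1 are given in each tested comparison. Predicted genes, clones, olfactory and vomeronasal receptors, small RNAs and sex-linked markers were counted and not named.

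Arrays were compared by Pearson r across genes and by principal components. Genes with an effect of day at adjusted p 0.05 were put into 6 clusters by k-means with 50 starts on centred and scaled values, and lists were tested in each cluster with Fisher's exact test against all genes tested. Alternatives were no filter, a filter at the 50th percentile, quantile normalization again, centring each array, no variance trend, a robust prior, the mean of a gene's probe sets, other thresholds, no day block or no culture term, other cluster numbers, other correlation measures, leaving out each day or array, and day 0 entered midway between the cultures. Figures were drawn with matplotlib.

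The fits were tested on simulated data with the means and residual spread of the 15710 genes and 200 changed genes. For the culture comparison 47.8% of 1.5-fold, 91% of 2-fold and 98.5% of 4-fold changes were recovered, with 11 false calls among 15510 unchanged genes. For day 25 against day 15 the shares were 9%, 62.7% and 97%, with 2 false calls. For the change of the culture difference they were 0%, 11.9% and 86.4%, with 10 false calls. The simulated genes were independent and each was shifted by the same amount in all arrays concerned. These shares therefore do not give the power for real differences that vary from day to day. In the real values 81 genes differed between cultures with one sign on all 4 days and at least 2-fold on average, and 1 gene passed. Signal over background and the number of arrays limit the precision of all values.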

Results

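Expression was measured on 9 arrays of secondary mouse embryonic fibroblasts, which are fibroblasts derived from an earlier reprogrammed line (6C) and carry reprogramming genes that doxycycline switches on. The cells came from a mixed background, mainly R1 and ICR. There was 1 array of the starting cells at day 0. Days 2, 6, 15 and 25 each had 1 array of an adherent culture and 1 of a suspension culture, and the labels place the day 25 cells without doxycycline. The day 0 array is labelled as with doxycycline, which was added on that day, and whether these cells had been exposed to it is not given in the sources used here. The study asked how reprogramming compares between these culture conditions. Array medians over 35557 probe sets lay between 7.43 and 7.61 on the log2 scale, and 15710 genes were tested. No group had a replicate, so each tested difference was set against the residual of a model of day and culture. This model was additive except where the change of the culture difference was tested. Differences on single days had no replicate check.

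The day 0 array was closest to day 2 adherent, with a Pearson r of 0.939 across genes. In 7 of the 8 later arrays the closest array was the other culture of the same day. The exception was day 2 adherent, whose r was 0.968 with day 6 adherent and 0.967 with day 2 suspension. Between the cultures of one day, r was 0.978 on day 6, 0.985 on day 15 and 0.975 on day 25. Genes are not independent replicates, so these coefficients carry no p-value. The first principal component held 57.3% of the variance and the second 19.8%.

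**Figure D1:**
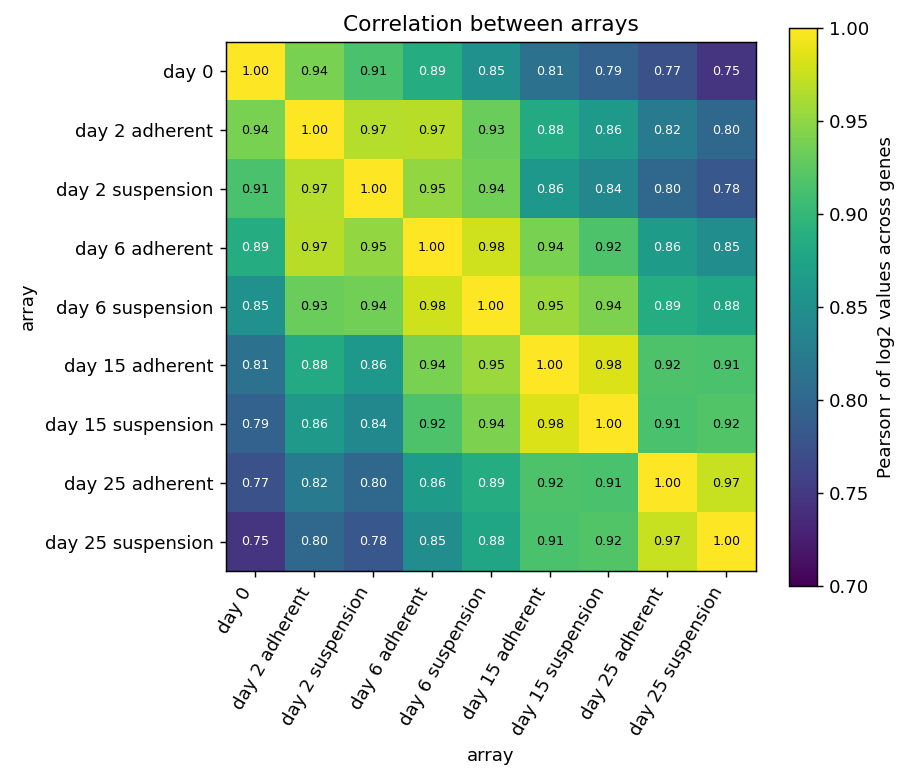
Pearson r of log2 values across 15710 genes for every pair of the 9 arrays, with arrays in order of day on both axes. The cultures of one day lie between 0.967 and 0.985.

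Anxa3, a calcium-dependent phospholipid-binding protein, was lower in suspension on all 4 days, by -2.65 ± 0.147 log2 units (SE, 4 matched days). It was the only one of 15710 genes to pass (limma, adjusted p = 0.0172). Genes of the contractile machinery and targets of the SRF and YAP regulators had the largest difference of any list, with a median of -1.38 over 18 members. Pou5f1, an integrated reprogramming factor and core pluripotency gene, differed by 0.39 ± 0.0665 in favour of suspension, without passing (adjusted p = 0.322).

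The 9 further genes with the smallest p in the lower direction did not pass. They included Thbs1 (thrombospondin, -2.78), Vnn1 (-1.54), Amotl2 (-1.39), Vgll3 (a TEAD cofactor, -1.28), Ccdc68 (-1.17), Pvr (-1.13), Plaur (the urokinase receptor, -1.04), Sgcd (-0.81) and Tbx20 (-0.79), with adjusted p between 0.123 and 0.322. In the higher direction none passed. The 10 with the smallest p were Nr0b1 (1.75), Slc7a8 (1.09), Cyria (1.02), Rasgrp1 (0.84), Kcnk5 (0.66), Pgap1 (0.63), Nlgn3 (0.61), Aldh9a1 (0.41), Pou5f1 and Fth1 (ferritin heavy chain, 0.28), each with adjusted p = 0.322. Sox2 (0.54), Nanog (0.44), Myc (0.41) and Thy1 (0.085) did not pass either, nor did Klf4 (-0.005) and Cdh1 (0.006), whose signs turned after centring and after quantile normalization, respectively. Sox2 differed by 1.76 on day 15 and by 0.015 to 0.244 on the other days. Nanog differed by 1.72 on day 6 and by -0.255 to 0.288 otherwise. Myc differed by 1.53 on day 25 and by -0.008 to 0.116 otherwise.

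In the contractile list 0 of 18 members passed over all genes and 17 fell when adjusted over the list alone. Thbs1 differed by -2.78, Tagln by -2.76, Acta2 (smooth muscle actin) by -2.56 and Cnn1 by -2.28. The list was lower by camera with its preset correlation (adjusted p = 5.31e-19), and not called at adjusted p = 0.584 with an estimated correlation. Integrin and focal adhesion genes had a median of -0.40, led by Parva (-1.01) and Itga3 (-0.95). Of 16 members 0 passed over all genes and 8 fell when adjusted over the list alone (preset adjusted p = 4.55e-05; adjusted p = 0.513 with an estimated correlation). Skeletal and cardiac muscle markers, which share actin and sarcomere genes with other contractile cells, had a median of -0.11, with Acta1 at -0.99 and Des at -0.48. Of these 9 markers 0 passed over all genes and 2 fell when adjusted over the list alone (preset adjusted p = 0.00277; adjusted p = 0.568 with an estimated correlation).

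Pluripotency genes had a median of 0.27 over 26 members, led by Nr0b1 and Tdgf1 (1.01). Of the 26, 0 passed over all genes and 1 rose when adjusted over the list alone (preset adjusted p = 5.77e-04; adjusted p = 0.584 with an estimated correlation). Primed epiblast genes, which mark the later form of pluripotency, had a median of 0.45, led by Lef1 (0.80) and Zic2 (0.77). None of their 9 members passed in either adjustment (preset adjusted p = 0.00653; adjusted p = 0.694 with an estimated correlation). Fibroblast markers and matrix genes had a median of -0.001 and a mean of -0.13. Their members went both ways, with Lum at 1.28 and Timp3 at -1.0. Of 21, 0 passed over all genes, while 1 rose and 7 fell when adjusted over the list alone (preset adjusted p = 0.0136, lower; adjusted p = 0.694 with an estimated correlation).

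Across all genes 1388 had an unadjusted limma p under 0.05, of which 623 were higher and 765 lower in suspension, against 786 by chance. The sign was the same on all 4 days for 2882 genes (18.3%, against 12.5% by chance). The Anxa3 call was lost when any one of the 4 days was left out (adjusted p between 0.0563 and 0.212, at differences of -2.51 to -2.76) and without the day block, where 0 genes passed. Without day 6 the pluripotency median was 0.15. The primed epiblast call was lost without day 25 (median 0.08, adjusted p = 0.354), and its median was 0.68 without day 2. The fibroblast call was lost without day 15 (median 0.13, adjusted p = 0.188) and without day 25 (median -0.06, adjusted p = 0.0934), and its median was -0.31 without day 2 and -0.15 without day 6.

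**Figure D2:**
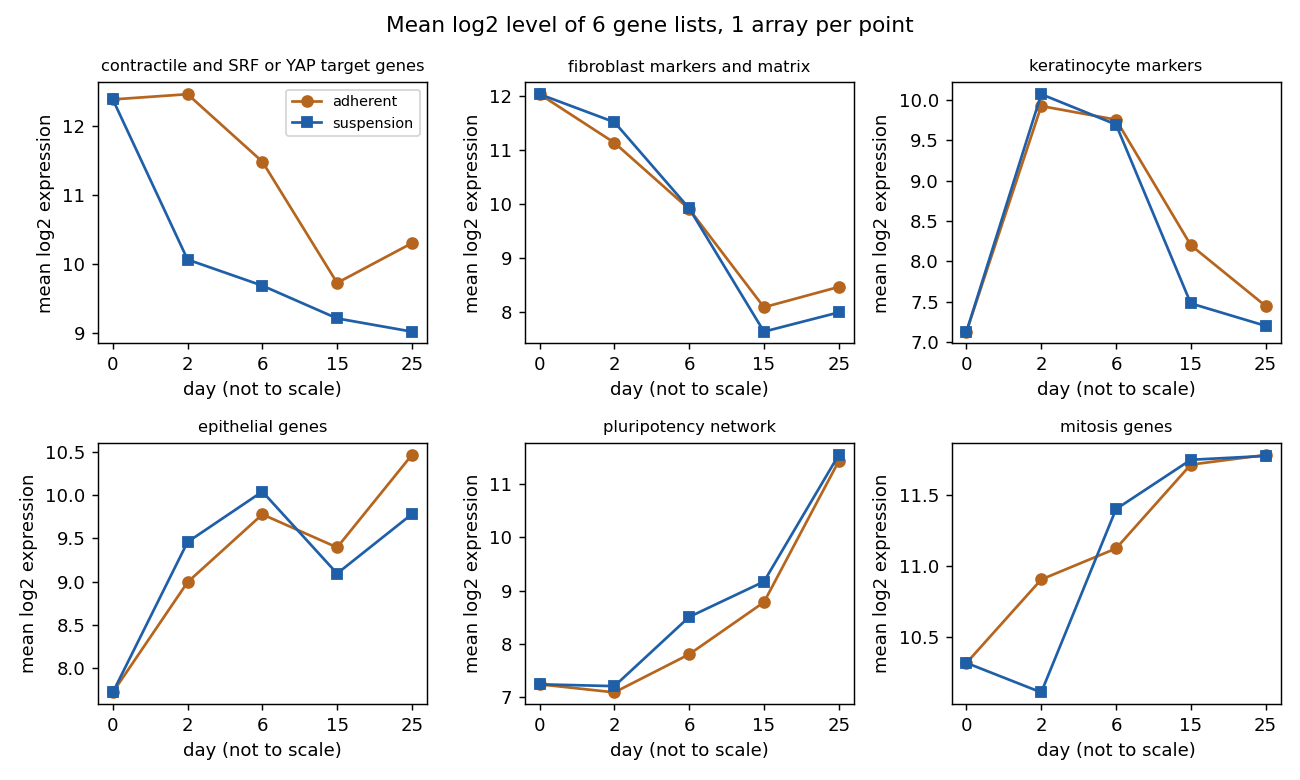
Mean log2 level of 6 gene lists (vertical axes) on each day (horizontal axes, days not to scale), with adherent cultures as circles, suspension cultures as squares and 1 array per point; day 0 is 1 array, joined to both lines. The contractile list stood at 12.47 in adherent and 10.06 in suspension culture on day 2, and keratinocyte markers were at 7.13 on day 0 and about 10 on day 2 in both cultures.

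On day 2, 689 genes lay at least 2-fold apart between the cultures, 419 of them higher in suspension. Contractile genes were lower in suspension, with a list median of -2.04 that lay below all of 10000 random lists of matched expression. The largest differences were Cnn1 (-5.12), Ppbp (-4.84), Ankrd1 (-4.43), Tagln (-4.34) and Myl9 (-4.30). In the other direction stood Igfbp5 (4.2), Krt1 (4.15), Serpina3n (3.93), Mmp13 (collagenase 3, 3.91) and Sparcl1 (3.58). Mitosis genes were lower in suspension for 19 of 19 members on day 2 (median -0.84) and higher for 19 of 19 on day 6 (median 0.27). DNA replication genes had medians of -0.47 and 0.33 on these days.

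On day 6, 392 genes were at least 2-fold apart, 254 of them lower in suspension. Pluripotency genes were higher, with a median of 0.36; of 26 members 17 were higher, 8 of them at least 2-fold, and 9 lower. Tdgf1, a Nodal co-receptor, stood at 10.25 in suspension and 6.62 in adherent culture, Fbxo15 at 8.88 and 6.01, Nr0b1 at 11.79 and 9.16, and Nanog at 10.83 and 9.10. The largest differences were Mmp3 (stromelysin 1, a matrix protease, 4.19), Lcn2 (lipocalin 2, 3.78), Saa3 (3.78), Lbp (3.68) and Tdgf1 (3.63). The senescence-associated list, which holds Mmp3, had a median of 1.0, with 5 of 10 members at least 2-fold higher and 3 lower. Efemp1 (-3.93), Myl9 (-3.82), Tagln (-3.68), Ppbp (-3.63) and Thbs1 (-3.53) were the lowest.

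On day 15, 157 genes were at least 2-fold apart, the fewest of the 4 days. Tfap2d (2.98), Jam2 (2.62), Nr0b1 (2.20), Lonrf3 (2.13) and Zic1 (1.94) were higher in suspension. Mme (-2.51), Lama4 (-2.36), Anxa3 (-2.35), Tgm1 (-2.32) and Thbs1 (-2.11) were lower. Sox2 stood at 9.79 in suspension and 8.03 in adherent culture, and was at 13.33 and 13.32 on day 25. Keratinocyte markers were lower in suspension for 10 of 10 members, with a median of -0.51. Fibroblast markers were lower for 18 of 21 members (median -0.46), epithelial genes for 18 of 21 (-0.20) and contractile genes for 16 of 18 (-0.31), and pluripotency genes were higher for 19 of 26 (0.28).

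On day 25, 342 genes were at least 2-fold apart, 220 of them lower in suspension. Primed epiblast genes were higher in suspension for 9 of 9 members (median 1.56), including Foxd3 (2.12), Fgf5 (2.12) and Lef1 (1.85). Eomes (2.43) and Mixl1 (2.15), early mesendoderm regulators, and Pim2 (2.01) were also among the highest. Srgn (-4.11), Krt18 (-3.82), Acta2 (-3.72), Thbs1 (-3.45) and Anxa2 (-3.37) were the lowest. Markers of extraembryonic endoderm were lower for 14 of 14 members (median -0.68), with Cubn at -3.12 and Lama1 at -2.68, and trophoblast markers had a median of -0.87, with Krt7 at -2.28 and Gata3 at -1.33. Hypoxia response genes had a median of -0.73, with P4ha1 at -1.72 and Vegfa at -1.49, and imprinted genes one of -0.56, with Igf2 at -2.74 and Sgce at -2.11. Pluripotency genes had a median of 0.12 and none was 2-fold apart.

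**Figure D3:**
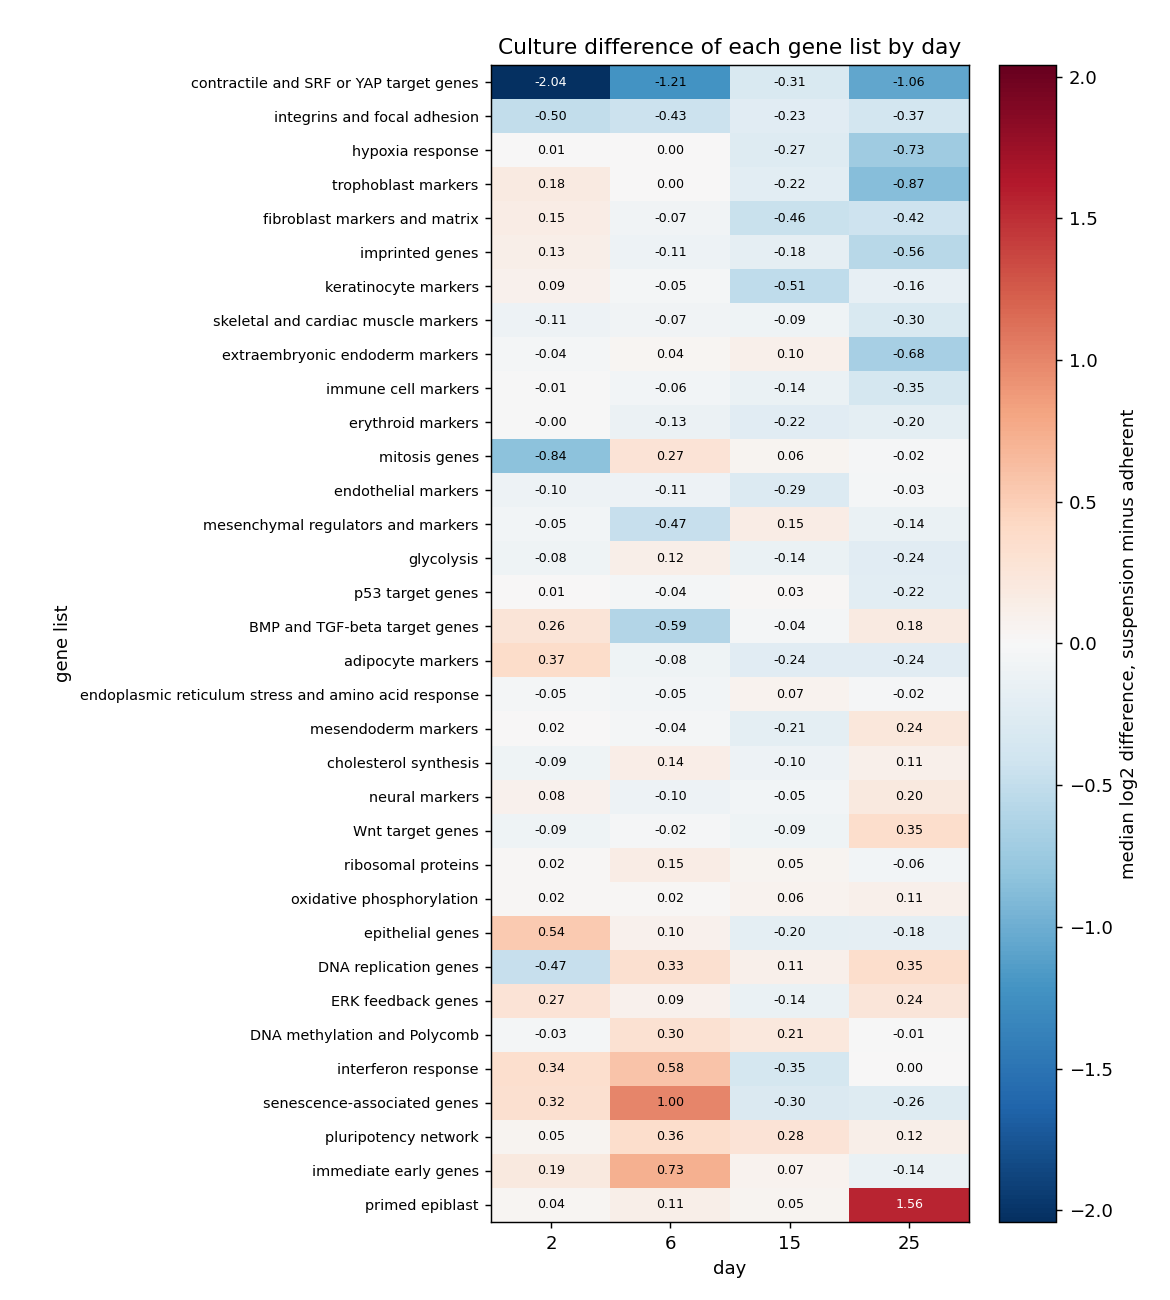
Median log2 difference, suspension minus adherent, of each of 34 gene lists (rows) on each of 4 days (columns), from 1 array per culture and day. The contractile list is negative on every day, at -2.04, -1.21, -0.31 and -1.06, and primed epiblast genes reach 1.56 on day 25.

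From day 0 to day 2, 6 of 10 keratinocyte markers and 6 of 21 epithelial genes rose. Krtdap rose by 6.66 ± 0.571 log2 units (SE; 2 arrays against 1), Krt6b by 6.47, Alox12b by 6.37, Ly6g6c by 6.14, Krt6a by 6.13, Krt14 (a basal keratin) by 5.84, Serpinb5 by 5.75, Cnfn by 5.55 and Krt16 by 5.49. Pou5f1 rose by 5.98 ± 0.134 (adjusted p = 5.56e-05). Transgene and endogenous transcripts were not told apart, because the position of the probes was not used here. The genes that fell most were Aspn (-4.00), Sfrp2 (-3.38), Rtl3 (-3.33), Lrrtm3 (-3.11), Ptn (-2.93), C1qtnf3 (-2.80), Abi3bp (-2.79), Eln (elastin, -2.73), Lgr5 (-2.71) and Igsf10 (-2.60).

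In all, 578 genes passed (limma, adjusted p under 0.05), 392 higher and 186 lower on day 2. Of 10 keratinocyte markers 6 rose over all genes, 7 adjusted over the list alone and 0 fell (preset adjusted p = 1.93e-08; adjusted p = 0.583 with an estimated correlation). Of 21 epithelial genes 6 rose and 0 fell over all genes, and 7 rose and 1 fell adjusted over the list alone, with Krt8 at 5.26, Dsp at 5.06 and Cdh1 (E-cadherin) at 3.71 (preset adjusted p = 1.50e-05; adjusted p = 0.583 with an estimated correlation). Cholesterol synthesis genes fell for 4 of 16 members, and for 12 adjusted over the list alone, with Insig1 at -1.58 and Lss at -1.18 (preset adjusted p = 4.00e-08; adjusted p = 0.583 with an estimated correlation). Interferon response genes fell for 3 of 12, and for 8 adjusted over the list alone, with Usp18 at -1.90 (not passed) and Stat2 at -1.63 (preset adjusted p = 1.50e-05; adjusted p = 0.583 with an estimated correlation). Thy1, Nanog, Sox2, Klf4 and Myc did not pass, at -0.84, -0.61, 0.15, 0.09 and 0.69. These changes refer to the fitted adherent level, since day 0 was entered as adherent. With day 0 midway between the cultures, which compares it with the mean of both day 2 arrays, the values were -0.79, -0.39, 0.42, 0.09 and 0.90, and Pou5f1 rose by 6.17.

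Day 0 is 1 array, assumed to vary like the others. The count dropped to 107 without day 15 suspension, 111 without day 15 adherent, 217 without day 6 suspension and 218 without day 6 adherent. The epithelial members that rose went to 1 without either day 15 array and 2 without either day 6 array. The cholesterol synthesis members that fell went to 2 without day 2 suspension, 1 without either day 6 array and 0 without either day 15 array, where the interferon members that fell also went to 0. The keratinocyte members numbered 6 or 7 throughout.

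Between days 2 and 6, 6 of 26 genes of the pluripotency network rose and 5 of 21 fibroblast markers fell. Apela, a peptide hormone of early embryos, rose by 4.60 ± 0.276 (SE, 2 arrays each day), Nr0b1 by 4.04, Epcam (an epithelial adhesion protein) by 3.35, Shisa3 by 3.23, Nanog by 3.14 (adjusted p = 0.0262), Alpl (alkaline phosphatase) by 2.91, Esrp1 (an epithelial splicing factor) by 2.90, Sall4 by 2.76, Aim2 by 2.69 and Slain1 by 2.54. Anxa10 (-3.48), Lrrc17 (-3.45), Rarres1 (-2.95), Ogn (-2.93), Gjb2 (-2.75), Abi3bp (-2.70), Anpep (-2.58), Cpa4 (-2.55), Aspn (-2.51) and Fbln5 (-2.5) fell. Thy1, a fibroblast surface marker, fell by 1.81 (adjusted p = 0.0176). Pou5f1 rose by 0.68 (adjusted p = 0.0317). Cdh1 (0.92), Sox2 (0.795), Klf4 (0.21) and Myc (-0.003, and 0.024 after quantile normalization) did not pass.

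Of 538 genes past the threshold, 191 rose and 347 fell. The pluripotency list had 6 of 26 members higher and 0 lower, with 8 adjusted over the list alone (preset adjusted p = 3.76e-06; adjusted p = 0.35 with an estimated correlation). Fibroblast markers fell for 5 of 21, and for 17 adjusted over the list alone; the largest differences, Postn at -2.97, Col6a3 at -1.99 and Lum at -1.94, did not pass (preset adjusted p = 2.52e-14; adjusted p = 0.247 with an estimated correlation). Mesenchymal regulators fell for 5 of 15, and for 12 adjusted over the list alone, with Tgfb3 at -2.01 and Snai2 at -1.88 (neither passed) and Cdh11 at -1.88 (preset adjusted p = 2.06e-11; adjusted p = 0.308 with an estimated correlation). Mitosis genes had a median of 0.78 with 0 of 19 past the threshold over all genes and 12 rising adjusted over the list alone, led by Aurkb (0.98) and Kif11 (0.97), with preset adjusted p = 3.69e-07 and adjusted p = 0.663 with an estimated correlation. Their mean level went from 10.91 to 11.12 in adherent and from 10.11 to 11.40 in suspension culture.

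The arrays of days 15 and 25 do not enter the difference between days 2 and 6. Its median over all genes stayed at 0.058 without any one of them, so there only the estimated spread and its degrees of freedom changed. The count of genes past the threshold moved with each array left out. It was 0 without either day 15 array, 1 without day 6 suspension, 113 without day 2 suspension, 160 without day 6 adherent, 334 without day 25 adherent, 338 without day 25 suspension and 1184 without day 2 adherent. Without day 6 suspension or either day 15 array, 0 pluripotency, fibroblast or mesenchymal members passed. Without day 2 suspension these numbered 3, 2 and 2. Without day 6 adherent 2 fibroblast and 3 mesenchymal members passed, and without day 2 adherent 11 fibroblast members. The mitosis median was 0.295 without day 2 suspension, 0.496 without day 6 suspension and 1.26 without day 2 adherent. Adjusted over the list alone, 19 mitosis genes rose without day 2 adherent, 12 without day 6 adherent and 0 without any one of the other 6 arrays.

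From day 6 to day 15, 5 of 10 keratinocyte markers and 11 of 21 fibroblast markers fell. Bgn (biglycan) fell by 6.16 ± 0.659, Lox (a collagen cross-linking oxidase) by 5.58, Ccdc80 by 5.24, Krt6b by 5.08, Timp2 by 4.84, Serpinb5 by 4.73, Asprv1 by 4.71, Cnfn by 4.60, Igfbp7 by 4.42 and Inhba by 4.41. Sfrp2 rose by 3.27, Cecr2 by 3.09, Prtg by 2.86, Kit by 2.73, Bche by 2.71, Rbpms by 2.65, En2 by 2.57, Olig3 by 2.45, Klhl13 by 2.44 and Otx2 by 2.41. En2 and Olig3, regulators of neural development, were back at 7.77 and 6.16 in the adherent array of day 25. Nanog rose by 2.33 (adjusted p = 0.0439) and Thy1 fell by 2.19 (adjusted p = 0.00566), while Sox2 (1.17), Pou5f1 (-0.14), Klf4 (-0.06), Myc (-0.06) and Cdh1 (-0.93) did not pass.

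Here 163 genes rose and 542 fell, 705 in all. Of 21 fibroblast markers 11 fell, 15 adjusted over the list alone and 0 rose, with Lox at -5.58 and Dcn at -4.35 (preset adjusted p = 9.71e-15; adjusted p = 0.257 with an estimated correlation). Immediate early genes, the first transcribed after a growth stimulus, fell for 6 of 11 and for 10 adjusted over the list alone, led by Dusp1 (-2.49), Fos (-2.16) and Fosb (-2.13), at preset adjusted p = 2.00e-09 and adjusted p = 0.35 with an estimated correlation. Keratinocyte markers fell for 5 of 10, and for 6 adjusted over the list alone, with Krt6a at -4.07 and Krt14 at -3.91 (preset adjusted p = 1.35e-07; adjusted p = 0.419 with an estimated correlation). Senescence-associated genes fell for 4 of 10, and for 6 adjusted over the list alone, with Mmp13 at -4.01 and Mmp3 at -3.81 (neither passed) and Ccl2 at -3.36 (preset adjusted p = 2.21e-05; adjusted p = 0.419 with an estimated correlation). Pluripotency genes rose for 6 of 26, led by Nanog (2.33), Dppa5a (2.08), Utf1 (2.02) and Sall4 (1.90), while 12 rose and 2 fell adjusted over the list alone (preset adjusted p = 4.67e-06; adjusted p = 0.35 with an estimated correlation).

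The count was 44 without day 15 suspension, 102 without day 6 adherent, 125 without day 15 adherent, 282 without day 6 suspension, 1311 without day 2 adherent and 1314 without day 2 suspension. The fibroblast members that fell went to 6 without day 6 adherent or day 15 adherent and 4 without day 15 suspension. The immediate early members went to 3 without day 6 adherent and 1 without day 6 suspension or either day 15 array. The keratinocyte members went to 3 without either day 6 array and 2 without day 15 suspension. The senescence-associated members went to 2 without day 6 suspension and 0 without day 6 adherent or either day 15 array. The pluripotency members that rose went to 3 without day 15 adherent, 1 without day 6 adherent and 0 without day 15 suspension.

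**Figure D4:**
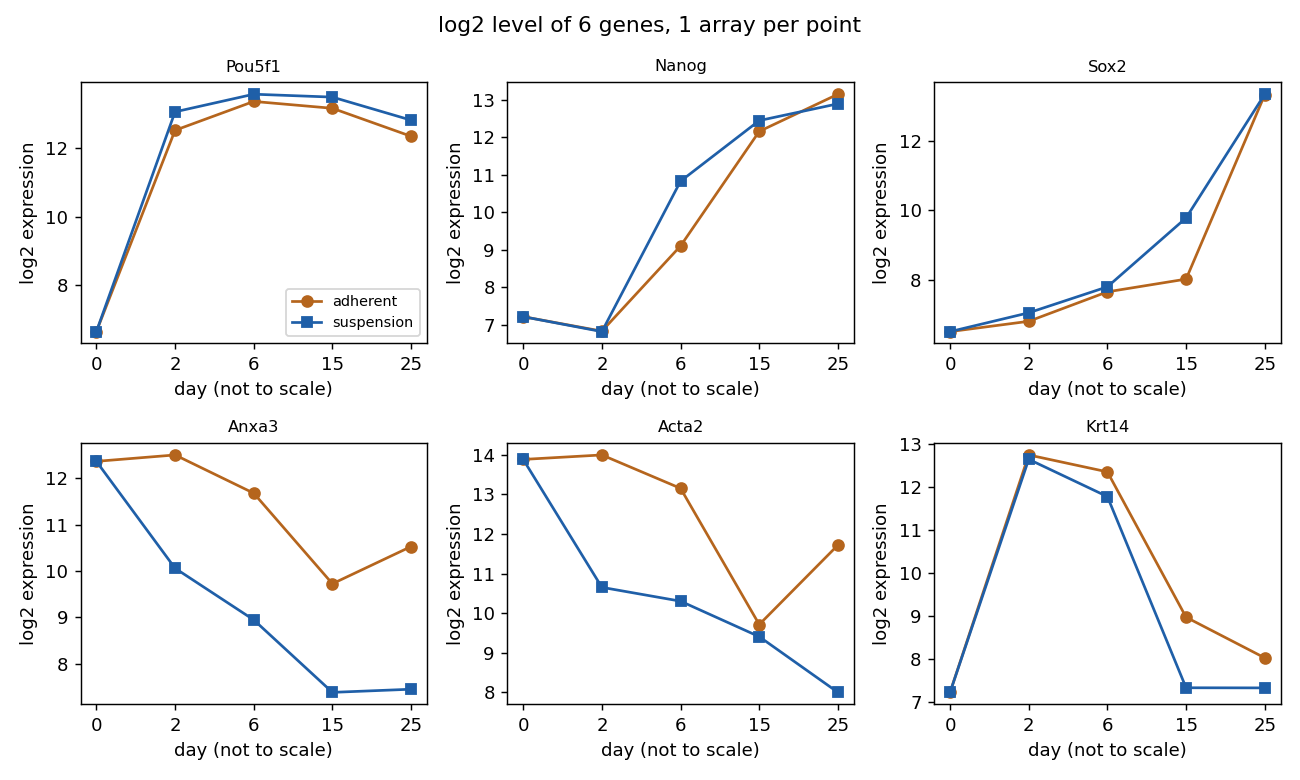
log2 level of 6 genes (vertical axes) on each day (horizontal axes, days not to scale), with adherent cultures as circles, suspension cultures as squares and 1 array per point; day 0 is 1 array, joined to both lines. Pou5f1 was at 6.63 on day 0 and 12.53 in adherent culture on day 2, whereas Sox2 reached 13.32 only on day 25; Anxa3 was lower in suspension on each of the 4 days.

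Between days 15 and 25, 20 of 26 genes of the pluripotency network rose. The arrays of day 25 are labelled without doxycycline and those of day 15 with it, so day and doxycycline cannot be told apart here. Usp26 rose by 5.70 ± 0.165, Car4 by 5.33, Pla2g1b by 4.73, Lncenc1 by 4.69, Dppa5a by 4.67, Sox2 by 4.42 (adjusted p = 0.00167), Dnmt3l by 4.42, Ephx2 by 4.37, Triml2 by 4.28 and Morc1 by 4.2. Krtdap (-5.22), Akr1c18 (-4.67), Tfap2a (-4.36), Meis2 (-4.30), Cd109 (-4.28), Tbx15 (-4.09), Nfix (-4.01), Prrx1 (-3.77), Emp1 (-3.62) and Ptprz1 (-3.52) fell. Myc fell by 1.66 and Pou5f1 by 0.75, Cdh1 rose by 1.15, and Thy1 rose by 1.72 (adjusted p = 0.00326). Nanog (0.72) and Klf4 (-0.47) did not pass.

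Of 2806 genes past the threshold, 1353 rose and 1453 fell. Pluripotency genes rose for 20 of 26 and 24 adjusted over the list alone, and 0 fell, led by Dppa5a (4.67), Dnmt3l (4.42) and Dppa2 (4.12), with preset adjusted p = 2.68e-19 and adjusted p = 0.258 with an estimated correlation. Epithelial genes rose for 6 of 21, with Krt18 at 2.66 (not passed) and Grhl2 at 2.56, while 9 rose and 1 fell adjusted over the list alone (preset adjusted p = 0.00129; adjusted p = 0.838 with an estimated correlation). Endothelial markers rose for 3 of 11, with Eng at 2.02 and Tek at -0.97 (not passed), while 6 rose and 1 fell adjusted over the list alone (preset adjusted p = 0.0109; adjusted p = 0.704 with an estimated correlation). Primed epiblast genes rose for 3 of 9 and fell for 1, against 6 and 1 adjusted over the list alone, led by Dnmt3b (2.38) and Nodal (2.20), with preset adjusted p = 0.0363 and adjusted p = 0.838 with an estimated correlation. Skeletal and cardiac muscle markers rose for 3 of 9 in both adjustments, with Des at 2.21 and Tnnt1 at 0.82 (preset adjusted p = 0.0363; adjusted p = 0.704 with an estimated correlation). Germline genes rose for 3 of the 3 tested, Hormad1 by 2.42, too few for the set test. The other genes of that list had no row or lay below the filter. The filter uses the mean over all 9 arrays, so a gene low on earlier days can pass it through a high day 25. Neural markers fell for 4 of 10, with Zic1 at -2.86 and Map2 at -2.04, but the list did not pass (preset adjusted p = 0.0794; adjusted p = 0.704 with an estimated correlation).

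The count was 710 without day 15 suspension, 1083 without day 15 adherent and 1750 without day 25 adherent. The pluripotency members that rose numbered between 15 and 22 over these fits. The epithelial members that rose went to 10 without either day 2 array, 3 without day 15 adherent and 2 without day 15 suspension or day 25 adherent. The primed epiblast members that rose went to 6 without day 25 adherent, 1 without day 15 adherent and 0 without day 15 suspension. The muscle members went to 1 without either day 15 array, the endothelial members to 1 without day 15 suspension, and the neural members that fell to 2 without day 15 adherent or day 25 adherent and 1 without the suspension array of either day.

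Compared with the starting cells, 19 of 21 fibroblast markers were lower and 25 of 26 genes of the pluripotency network higher on day 25. Bex1 rose by 7.07 ± 0.5 (SE, 2 arrays against 1), Dppa5a by 6.76, Apela by 6.56, Sox2 by 6.53, Utf1 by 6.18, Tdgf1 by 6.00, Usp26 by 5.81, Pou5f1 by 5.77, Fbxo15 by 5.77 and Lncenc1 by 5.73. Nanog rose by 5.58 and Cdh1 by 4.85. These are again changes to the fitted adherent level. With day 0 midway between the cultures, Sox2 rose by 6.80, Tdgf1 by 6.50, Nanog by 5.80 and Cdh1 by 4.86. Aspn (-7.67), Lox (-7.37), Ogn (-6.93), Prrx1 (-6.64), Tbx15 (-6.28), Osmr (-6.17), Ccdc80 (-6.08), Abi3bp (-6.01), Lrrc17 (-5.96) and Edil3 (-5.89) fell, and Thy1 fell by 3.11. Klf4 (-0.24) and Myc (-1.04) did not pass.

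Of 5757 genes past the threshold, 2841 rose and 2916 fell. Pluripotency genes rose for 25 of 26, and for all 26 adjusted over the list alone, led by Dppa5a and Utf1 (preset adjusted p = 1.29e-15; adjusted p = 0.315 with an estimated correlation). Mesenchymal regulators fell for 15 of 15 in both adjustments, with Prrx1 at -6.64, Tgfb3 at -5.59 and Cdh11 at -5.58 (preset adjusted p = 3.38e-09; adjusted p = 0.315 with an estimated correlation). Fibroblast markers fell for 19 of 21, and for 20 adjusted over the list alone, led by Lox and Lum (-5.55), with preset adjusted p = 1.42e-11 and adjusted p = 0.315 with an estimated correlation. Epithelial genes rose for 14 of 21, and for 16 adjusted over the list alone, led by Cldn6 at 5.02 and Cdh1 at 4.85 (preset adjusted p = 5.59e-06; adjusted p = 0.469 with an estimated correlation). Mitosis genes rose for 17 of 19, and for 19 adjusted over the list alone, with Top2a at 2.39 and Bub1 at 2.28 (preset adjusted p = 1.79e-06; adjusted p = 0.563 with an estimated correlation). DNA methylation and Polycomb genes rose for 10 of 13 and fell for 1, against 12 and 1 adjusted over the list alone, led by Tet1 (3.66) and Jarid2 (3.16), at preset adjusted p = 9.56e-05 and adjusted p = 0.399 with an estimated correlation. Centring each array on its median shifted the median of all genes from 0.03 to -0.11 and the share of higher calls from 49.3% to 38.6%.

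Of 7170 genes with an effect of day, k-means made 6 clusters, and 16 of the lists were over-represented in at least 1 of them by Fisher's exact test. Genes are not independent replicates, and the background was all genes tested, so an effect of day alone can over-represent a list. The p-values below only describe the overlap. With 4 and 8 clusters the grouping matched the main one in part (adjusted Rand index 0.64 and 0.673, where 1 is the same grouping). Fibroblast markers fell into a cluster of 1622 genes that declined to day 15 (19 of 21, adjusted p = 5.83e-15). Keratinocyte markers lay in a cluster of 545 genes that peaked on days 2 and 6 (6 of 10, adjusted p = 1.29e-05), as did 6 of 21 epithelial genes (adjusted p = 0.00156). Pluripotency genes lay in a cluster of 1227 genes highest on day 25 (18 of 26, adjusted p = 6.04e-13), and mitosis genes in one of 1795 genes that climbed to day 15 (18 of 19, adjusted p = 1.77e-14).

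The last comparison asked whether the culture difference itself changed between the early days (2 and 6) and the late days (15, with doxycycline, and 25, without it). Contractile genes were less far below adherent culture on the late days, by 0.98 in median, led by Cnn1 (3.94) and Myl9 (3.84), although their median on day 25 (-1.06) was near that of day 6 (-1.21). Epithelial genes moved the other way, by -0.81, led by Krt8 (-2.15) and Krt18 (-2.00), and senescence-associated genes by -1.16, led by Mmp13 (-4.07) and Mmp3 (-3.97). No gene passed: limma called 0 of 15710 genes, with 1122 at an unadjusted p under 0.05 against 786 by chance, and the lowest adjusted p was 0.0708. Myc stood at 0.83, Sox2 at 0.69, Thy1 at 0.435, Klf4 at -0.14, Cdh1 at -0.65, Nanog at -0.84 and Pou5f1 at 0.02, which was -0.03 after quantile normalization. Adjusted over the list alone, 8 contractile genes rose and 8 epithelial and 5 senescence-associated genes fell. These lists passed with the preset correlation (adjusted p = 1.75e-08, 1.75e-08 and 3.85e-05) and not with an estimated one (adjusted p = 0.715 with an estimated correlation for each). Of 34 lists tested, 2 were called higher and 10 lower.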

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

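All tests of explanations in this part were chosen after the results were seen, except the counts of other groupings of the arrays.

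The culture difference changed between early and late days for 12 lists by camera with its preset correlation, a test of the difference itself, and for none with an estimated correlation. The medians were higher on late days for contractile (0.98) and DNA replication genes (0.33). They were lower for senescence-associated (-1.16), epithelial (-0.81), keratinocyte (-0.54), trophoblast (-0.51), fibroblast (-0.50), hypoxia (-0.39), interferon (-0.36), immediate early (-0.35), extraembryonic endoderm (-0.34) and imprinted genes (-0.33). The late days combine day 15 with doxycycline and day 25 without it. On days 2, 6, 15 and 25 the medians were -2.04, -1.21, -0.31 and -1.06 for contractile genes and -0.47, 0.33, 0.11 and 0.35 for DNA replication genes, which were below 0 on day 2 alone. They were 0.32, 1.0, -0.30 and -0.26 for senescence-associated, 0.54, 0.095, -0.20 and -0.18 for epithelial, 0.09, -0.05, -0.51 and -0.16 for keratinocyte and 0.15, -0.07, -0.46 and -0.42 for fibroblast genes. Extraembryonic endoderm medians were -0.035, 0.04, 0.10 and -0.68, so that change came from day 25. Trophoblast, hypoxia and imprinted medians were -0.22, -0.27 and -0.18 on day 15 and -0.87, -0.73 and -0.56 on day 25. Among 7740 probe sets with several gene names or none, outside the comparisons above, 1898 changed between day 0 and day 25 (limma, adjusted p under 0.05), 1374 of them higher on day 25. Between cultures limma called 0 of these.

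Lower contractile genes in suspension were weighed against a smaller share of fibroblasts, which would lower fibroblast markers by about as much. On day 2 the fibroblast median lay 2.19 above the contractile median, more than the SD of the 21 markers (1.09), which argues against it for that day. The gap of 1.15 on day 6 (SD 1.18) and of 0.64 on day 25 (SD 0.745) leaves it open. This SD is the spread between markers and not the error of a median. On day 6, 10 of the 21 markers were higher in suspension and 11 lower. On day 15 the fibroblast median (-0.46) was as low as the contractile one (gap -0.156), as a smaller share would bring. Keratinocyte (median -0.51, 10 of 10 lower) and epithelial genes (-0.20, 18 of 21 lower) were lower too that day, while pluripotency genes were higher (0.28, 19 of 26). The fall on day 15 was therefore not particular to fibroblast markers. A shift in scale shared by genes of the same level is argued against by the contractile medians, at percentile 0 of random lists of matched expression on all 4 days. The list was taken up because its difference was the largest, so these percentiles are no separate support for the difference itself. Different anchorage of the cells, which the culture conditions name, may contribute, as a hypothesis found on the same data: the integrin and focal adhesion median lay at or below the 0.01 percentile of random lists on all 4 days.

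In the day 25 adherent array contractile genes stood above suspension again, with Acta2 at 11.72 against 8.0. Fibroblasts like those of day 0 would have to give 14.5% of the RNA to account for the contractile genes. Of the 21 fibroblast markers, 76.2% lay more than 1 log2 unit below the level that share would bring, with a median shortfall of 1.36. Lox (6.32) and Dcn (6.09) fell furthest short, and both stood below the level of the expression filter (6.37). Sparc and Pdgfra lay above the level needed, and Mmp2 and Fbln1 fell short by only 0.08 and 0.28. A shift in scale shared by genes of the same level on day 25 is argued against by the contractile median at percentile 0 of random lists of matched expression. That percentile restates the pattern and is no separate support for it. Cells of extraembryonic kind in the adherent culture may contribute. Extraembryonic endoderm and trophoblast medians both lay at percentile 0 of random lists, with 14 of 14 and 7 of 9 members lower in suspension. Fibroblast, hypoxia and imprinted medians lay at percentile 0 too, so this is not particular to extraembryonic markers. Peg10, which is in the trophoblast and imprinted lists, stood at 13.61 and Lama1 at 11.65 in the adherent array. Muscle (-0.30) and immune cell markers (-0.35) were lower in suspension too, and fibroblasts of another kind, such as feeder cells, stay open.

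Pluripotency genes were higher in suspension on day 6. A difference in scale would shift genes of the same level alike. The pluripotency median of 0.36 lay at percentile 100 of random lists of matched expression, which argues against such a shared shift. That percentile restates the pattern and is no separate support for it. A lower share of fibroblasts in suspension on day 6 could raise markers of all other cells alike, and the pluripotency median lay 0.408 above the keratinocyte median, beyond the SD of the keratinocyte members (0.24) but not of the pluripotency members (1.05). The fibroblast median on that day was -0.07, with 10 of 21 members higher, and the mesenchymal median was -0.47, with 13 of 15 lower, so a lower share cannot be told apart from a difference in the cells that express these genes. The culture condition itself stays open, as untested.

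When culture labels were swapped within days, the real labelling called 1 gene and the highest of the other 7 called 0; with 8 labellings in all the splits are too few for a share under 0.05. Over the 32 fitted splits of the 8 arrays into 4 and 4, 3 called at least 1 gene, the real one included, and the highest other called 52. The 2 splits with 52 genes kept both arrays of day 15 together and both of day 25. With the day block they compare the cultures of days 2 and 6 alone under their real labels. Their 52 genes therefore go with culture on those days, a comparison that was not planned, and are no measure of what chance would call. Other splits also keep the real labels on some days, so the count over all splits does not decide whether chance can be excluded. For the change of the culture difference, all 3 splits of the days called 0 genes (limma; 1122 at an unadjusted p under 0.05 for the real one), too few for such a share.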

How the results depend on the processing

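The list member counts and list-alone counts with each array left out, the list tests on members above log2 8 and day 0 entered midway between the cultures were chosen after seeing the data; all other alternatives were fixed before the data were examined. Signal over background and the absence of replicates limit all counts, and in each fit without 1 array the lone array of that day is assumed to vary like the others. The culture comparison is matched by day, and with 1 array per group there were no replicate numbers to pair by.

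Of 163 results for named genes, 163 kept their direction and side of the threshold with a robust prior or the mean of a gene's probe sets, 162 after centring each array, 160 after quantile normalization again, and 161 without the filter or without the variance trend, where 2 lost their call. With the filter at the 50th percentile 140 of 140 kept theirs, and without the culture term 124 of 130. With day 0 midway between the cultures 51 of 51 kept theirs, as did 27 of 27 list calls; 826 genes passed between days 0 and 2, of which 560 were among the 578, and 6311 between days 0 and 25, of which 5661 were among the 5757. Without the culture term these counts were 724 and 6080. Leaving out 1 array ended the most calls for day 15 suspension (43 of 130) and day 15 adherent (38), then day 6 suspension (28) and day 6 adherent (18), with fewer samples in each fit. The genes that turned direction lay near 0 and passed neither with all arrays nor where they turned; the cause was not tested. For culture, Klf4 was 0.016 after centring and -0.064 to 0.099 with a day left out, Cdh1 was -0.005 after quantile normalization and -0.185 to 0.195 with a day left out, and Thy1 was -0.063 to 0.165. With an array left out, Sox2 was -0.098 to 0.352 between days 0 and 2, Myc -0.282 to 0.277 between days 2 and 6 and -0.331 to 0.213 between days 6 and 15, and Klf4 -0.179 to 0.055 between days 6 and 15. After quantile normalization Myc was 0.024 between days 2 and 6, and Pou5f1 -0.032 for the change of the culture difference.

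Counts of genes past the threshold stayed within 1.5 times under the settings not named here. For culture, 1 gene became 0 without the day block and 0 with any day left out, where fewer samples enter. An adjusted p under 0.10 gave 1291 genes for day 2 against day 0, 1295 for day 6 against day 2, 1384 for day 15 against day 6 and 9 for the change of the culture difference, as a wider threshold must. Requiring a fold of at least 2, a stricter threshold, gave 1394 for day 25 against day 15 and 3739 for day 25 against day 0. With each array left out in turn the counts ran from 107 to 658 for day 2 against day 0, from 0 to 1184 for day 6 against day 2, from 44 to 1314 for day 15 against day 6, from 710 to 3122 for day 25 against day 15 and from 4570 to 6038 for day 25 against day 0; fewer samples enter each fit, but why the counts also went up was not tested. The day 2 arrays do not enter day 15 against day 6, whose median over all genes stayed at -0.006 without either of them. There only the estimated spread could change the count. Centring each array called 5581 genes between days 0 and 25, of which 5069 were shared, and 38.6% of them were higher on day 25, against 49.3% of the 5757. The genes at least 2-fold apart on single days, the closest arrays and the lists over-represented in clusters stayed within 1.5 times.

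Of the 86 list calls, 0 held with an estimated correlation, which gave 0 lists in each of the 7 comparisons. That form allows for more correlation between genes and also rests on the few residual degrees of freedom of the fit. In simulated data with independent genes, a list shifted by -0.5 had adjusted p = 6.89e-27 with the preset and 0.0436 with the estimated correlation (camera). The estimated form thus gave a far weaker result even without correlation between genes, although the simulated list still passed. With a single simulated list, how much of the loss in the real calls came from correlation between genes cannot be told. Centring kept 85, with the fibroblast culture median at 0.021 instead of -0.001 although camera still called the list lower, and the mean of probe sets 84. Members above log2 8 kept 12 of 14. The culture lists called numbered 9 to 15 with 1 day left out, against 15. The mitosis median, -0.172 with all days, was -0.278 to 0.086 over these fits and was higher in suspension without day 2 (adjusted p = 0.0377), and the extraembryonic endoderm median, -0.193 with all days, was -0.265 to 0.093 and above 0 without day 25 (adjusted p = 0.574). On the days left out the medians were -0.84 and -0.68, so each direction came from that day; for the other changes the cause was not tested.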

Other observations

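Several groups moved in ways the comparisons above do not describe. Thy1 and other fibroblast genes went down to day 15 and then partly up: Thy1 stood at 12.47 on day 0, 7.64 in the adherent array of day 15 and 9.13 in that of day 25, and in suspension at 7.71 and 9.66. Between days 15 and 25, 4 fibroblast markers rose and 2 fell over all genes, and 5 rose and 2 fell adjusted over the list alone, with Fbln1 at 2.21 and Mmp2 at 2.25, while Dcn fell by 1.85. The list as a whole did not pass (preset adjusted p = 0.125; adjusted p = 0.838 with an estimated correlation). Without day 15 adherent 2 of these markers rose and 0 fell, without day 15 suspension 1 rose and 1 fell, and without day 25 adherent 2 rose and 0 fell. Bgn, at 7.4 and 6.87 on day 15, stood at 11.14 in adherent and 8.22 in suspension culture on day 25.

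Across genes, the correlation of the culture difference was 0.391 between days 2 and 6, 0.006 between days 2 and 15 and 0.032 between days 2 and 25. It was 0.249 between days 6 and 15, 0.193 between days 6 and 25 and 0.22 between days 15 and 25; genes are not independent replicates. Interferon response genes had a median of 0.34 on day 2 and 0.58 on day 6 (11 of 12 members higher on each, with Rsad2 at 1.86 and Usp18 at 1.39 on day 6), -0.35 on day 15 (8 lower, 4 higher) and 0 on day 25 (6 each way). Immediate early genes had medians of 0.19, 0.73, 0.07 and -0.14 on days 2, 6, 15 and 25. These are differences between 1 array and 1 array, without a replicate check.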
